A study of Caenorhabditis elegans with 2 samples.

How the data were processed

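Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans larvae at the L3 stage, of both sexes, from strain OP43. Per the labels, this strain carries the unc-119(ed3) mutation and the integrated transgene wgIs43, which targets nhr-23, and the immunoprecipitation was directed at NHR-23 tagged with eGFP. NHR-23 is a nuclear hormone receptor of the ROR family that is required for molting. The labels give 2 biological replicates, which form 1 group, so no test between groups was possible. A control is named in the labels and is not used here.

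Per the deposited text files, peaks were called for each replicate against a control, and again on the pooled alignments of both replicates. The thresholded list was derived by the authors from the pooled list and both replicate lists by an irreproducible discovery rate (IDR) procedure. Such a procedure rests on how well peak ranks recur between lists. The aligner, the peak caller, the IDR threshold and all versions are not given in the sources used here. Per the labels, the lists exist on the assemblies ce11 and ce10. Each deposited peak carries a signal value, the peak caller's own measure per peak, and the −log10 of a q-value. The authors' signal value was used only to describe, rank or filter peaks within a list. The deposited −log10 q-values reached 1 shared maximum in each list, at 4944 of the 4944 thresholded peaks, and were therefore not used for ranking. The lists carry no read counts, so the sequencing depth of each replicate is unknown, and intervals given for shares of peaks cover counting error only. Replicates were called at a permissive threshold, with 30000 peaks for replicate 1 and 27191 for replicate 2, so a peak's presence in a replicate list alone is a weak criterion. The pooled list also held 30000 peaks. The lowest signal was 3.90 in replicate 1's list and 4.86 in the pooled list, against 2.00 in replicate 2's. The 30000 may thus be a limit on list size, and the sizes are not compared as numbers of calls. All 4944 thresholded peaks were the 4944 strongest peaks of the pooled list. Membership therefore followed the pooled signal rank and does not show that each peak recurred in both replicates.

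Coordinates are ce11 and 1-based. The gene annotation was Ensembl release 115 on WBcel235, the same assembly, with 19973 protein-coding genes on the nuclear chromosomes. The ce10 lists were used only where no annotation was needed. A gene was called bound when a thresholded summit lay from 1500 bp upstream to 500 bp downstream of one of its annotated transcript starts. Many C. elegans transcripts are trans-spliced, so annotated starts can lie downstream of the true ones, and neighbouring genes can share 1 peak. Locations and bound genes were compared with 1000 circular shifts of all summits along each chromosome, which keep the spacing between peaks. The smallest p these shifts can give is 0.001. The 25 gene lists and 13 sequence motifs were fixed before the data were examined, as were the tests. Lists were tested with Fisher's exact test over all protein-coding genes, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05; 0.5 was added to each cell of a table holding a 0 for the odds ratio. Motifs were searched on both strands within 50 bp of the summit and in 2 flanking windows of the same width centred 500 bp away, with Fisher's exact test, two-sided, and adjustment over the motifs. Signal ranks were compared with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Peaks and genes are not independent replicates, and these p-values describe the pooled list of 1 strain and stage.

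Named genes were chosen by a rule fixed in advance. It took the genes nearest to the 10 strongest peaks, up to 4 bound members with the strongest peaks from each list past the threshold, up to 2 from each other list, nhr-23 and unc-119, and the members of the molting, molting-cycle regulator and heterochronic lists. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used. The functions were tested on simulated data. Of 50 simulated lists of 20 genes bound at a raised rate, among 200 lists, 88% were called, and 1 unchanged list was called. The raised rate was a single value far above that of the unchanged lists. The 88% therefore does not give how often a list with a smaller rise would be called. All 1000 summits placed upstream of a chosen gene were assigned to it, and 1 of 40 uniform sets of summits fell under the threshold of the circular shifts.

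Alternatives fixed in advance were each replicate's own strongest peaks in place of the thresholded list, the stronger part of the thresholded list, other promoter windows, assignment to the nearest start, other gene backgrounds, other motif windows and backgrounds, other overlap criteria and the ce10 lists. The 5 microRNA members of the heterochronic list are not protein-coding genes and were outside the list test.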

Results

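ChIP-seq of eGFP-tagged NHR-23 in L3 larvae gave 4944 thresholded peaks from 2 biological replicates of 1 group. The peaks fell into 4928 distinct intervals, and their signal ranged from 34.2 to 967.1, with a median of 60.4. Replicate 1's list held 30000 peaks and replicate 2's list 27191. The lists give no read depth.

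The first question was whether both replicates held the same sites. Of replicate 1's 4944 strongest peaks, 67.1% had their summit in one of replicate 2's, and 68.6% in the other direction. The thresholded list was derived by the authors from both replicates and equalled the 4944 strongest peaks of their pooled list, so its presence in the replicate lists is no independent test. Of its summits, 4773 (96.5%, exact 95% interval 95.99 to 97.03) lay inside a peak of both full replicate lists. Among the 4944 strongest peaks of each replicate, both held 3332 thresholded summits (67.4%), and 127 (2.57%) were in neither. Across the 4773 peaks found in both lists, the signals of the replicates were correlated with a Spearman rho of 0.602 and a Pearson r of 0.624 on log10 values (permutation p = 1e-05 for each, the smallest possible, across peaks that are not independent). Without the 2 peaks farthest from the median, the correlation was r = 0.621. The strongest interval holds 4 summits, which all took the same pair of replicate signals. Leaving out 2 peaks therefore does not remove that interval from the correlation. The summits of matched peaks lay a median of 26 bp apart.

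The strongest peaks lay at the Hox gene egl-5, upstream of cdc-48.1 and upstream of ribosomal protein genes. The peaks ranked 1 and 2 shared an interval of 2666 bp on chromosome III, from 7814327 to 7816992, with signals of 967.1 and 892.5. It covered 94.6% of egl-5 (7814374 to 7817141, plus strand), held 4 summits, of which 2 lay in introns or unannotated parts of the gene, 1 in coding sequence and 1 in the 3' UTR, and ranked 1 in each replicate's list. The summits lay at least 554 bp downstream of the nearest start, outside the promoter window, so egl-5 is not among the bound genes. The peak ranked 3 lay 168 bp upstream of cdc-48.1, an AAA ATPase of protein quality control (chromosome II, 10563434 to 10563716, signal 760). The peaks ranked 4, 5 and 6 lay 280 bp upstream of rpl-3, 354 bp upstream of rpl-15 and 456 bp upstream of rpl-35, which encode proteins of the large ribosomal subunit. The remaining peaks of the 10 strongest lay 177 bp upstream of Y17G9B.5, 61 bp upstream of tasp-1, 125 bp upstream of ska-3 and 297 bp upstream of serp-1.1. All of these summits outside egl-5 were intergenic.

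**Figure D1:**
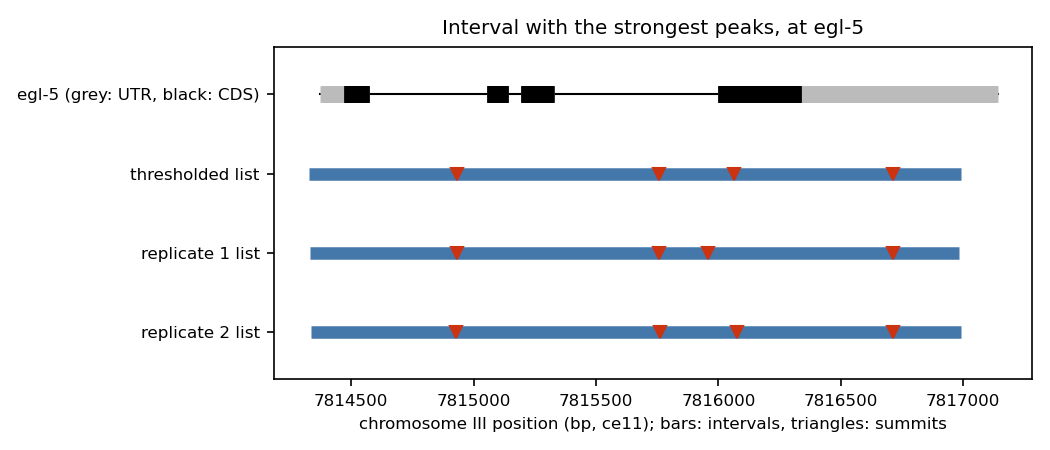
Map of the interval with the strongest peaks on chromosome III (ce11, bp), with the annotated egl-5 gene, the interval in the thresholded list and in each replicate's list as bars, and summits as triangles. The interval spans 2666 bp in the thresholded list, 2652 bp in replicate 1 and 2657 bp in replicate 2.

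Most summits lay in promoter windows, from 1500 bp upstream to 500 bp downstream of a start. These held 3190 summits (64.5%, exact 95% interval 63.2 to 65.9), against a mean of 39.3% in shifts (permutation p = 0.001), and windows from 500 bp upstream held 47.3%. Intergenic positions held 66.9% of summits against 36.97% in shifts, and 5' UTRs 4.21% against 1.43%. Coding sequence held 3.22% against 24.5%, introns or unannotated parts of genes 23.6% against 33.7%, and 3' UTRs 2.00% against 3.38% (permutation p = 0.001 for each location). The median summit lay −190 bp from the nearest protein-coding transcript start, and 72.7% lay upstream of it. The window assigned summits to 3883 of 19973 protein-coding genes (19.4%), against a mean of 1985 in shifts, and 1754 summits (35.5%) were assigned to no gene. With the 2472 strongest peaks alone, 2283 genes were bound.

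**Figure D2:**
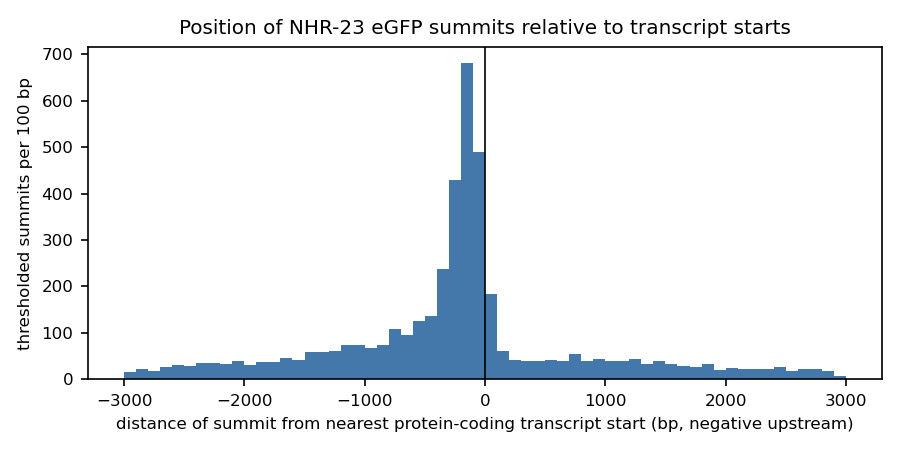
Number of thresholded summits per 100 bp (y axis) by signed distance from the nearest protein-coding transcript start (x axis, bp, negative upstream), within 3000 bp. The distribution peaks upstream of the start, and the median over all 4944 summits is −190 bp.

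Gene lists fixed in advance were then compared with all protein-coding genes. Of 25 lists, 8 were bound more often than other genes, 2 less often, and 15 did not pass the threshold. Against circular shifts 5 of these 15 lists had more bound members than the shifts gave: the molting list (9 against a mean of 2.44), cuticlin and precuticle genes (13 against 5.28), the col family (32 against 13.9), patched-related genes (9 against 2.94) and nuclear receptors (61 against 24.5), with adjusted permutation p of 0.00384, 0.00535, 0.00278, 0.00384 and 0.00278. All bound genes together were 1.96 times the mean of the shifts, so passing that test does not set a list apart from other genes. Ribosomal protein genes were bound at 68 of 76 (89.5%, against 19.2% of other genes; odds ratio 35.8, Fisher's exact test, adjusted p = 1.18e-38). With each summit assigned to its nearest start alone, 39 of 76 ribosomal protein genes were bound (51.3%, odds ratio 5.18, Fisher's exact test, adjusted p = 9.89e-11). Their 4 strongest peaks, at rpl-3, rpl-15, rpl-35 and rpl-20, ranked 4, 5, 6 and 7. The peak of rpl-20 is the one nearest to Y17G9B.5. The strongest peaks of bound ribosomal protein genes had a median signal percentile of 91.0, against 58.4 for other bound genes (permutation test, adjusted p = 0.00017), and no other of the 17 lists with at least 5 bound members passed that test. Among the 2472 strongest peaks hedgehog-related genes also passed it, with weaker peaks than other bound genes (adjusted p = 0.00018 by permutation test), and so did nuclear receptors with replicate 1's strongest peaks alone (adjusted p = 0.0246 by permutation test).

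Genes of the collagenous cuticle followed. All 6 furrow collagens, which build the annular furrows of the cuticle, were bound (adjusted p = 0.000269 by Fisher's exact test). Among genes with at least 1000 bp of upstream sequence, which leaves 2 furrow collagens, both bound, the call was lost (odds ratio 25.8, Fisher's exact test, adjusted p = 0.0586). Their strongest peaks lay 261 bp upstream of dpy-7 (rank 116), 352 bp upstream of dpy-10 (rank 219), 130 bp upstream of dpy-9 (rank 411) and 149 bp upstream of dpy-3 (rank 578). These 6 genes are also in the list of named cuticle collagens, of which 13 of 20 were bound (odds ratio 7.72, Fisher's exact test, adjusted p = 6.77e-05). Of 13 collagen processing genes 7 were bound (odds ratio 4.84, Fisher's exact test, adjusted p = 0.0148), among them dpy-11, a thioredoxin-like protein (rank 391), pdi-2, a protein disulfide isomerase (rank 466), dpy-31, an astacin procollagen protease (rank 546), and phy-2, a prolyl 4-hydroxylase (rank 1062). The collagen processing call was lost under 6 of the alternatives, among them either replicate's strongest peaks alone (adjusted p = 0.0582 and 0.0547 by Fisher's exact test). The wider col collagen family was bound at 32 of 156 (20.5%, odds ratio 1.07, Fisher's exact test, adjusted p = 0.792), including col-38 (rank 220) and col-62 (rank 851).

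Of 10 molting-cycle regulators, transcription factors and other regulators that act in the molting cycle, 7 were bound (odds ratio 9.68, Fisher's exact test, adjusted p = 0.00257). They were myrf-1 (rank 457), peb-1 (462), nhr-85 (1221), lin-42 (1345), myrf-2 (2276), grh-1 (2924) and nhr-25 (4059). The genes nhr-23, blmp-1 and bed-3 were not bound. The nearest summits to blmp-1 and bed-3 lay 1659 and 1680 bp from a start, outside the window, and blmp-1 was bound with either replicate's strongest peaks alone. Of 12 protein-coding heterochronic genes, which time larval development, 8 were bound (odds ratio 8.30, Fisher's exact test, adjusted p = 0.00197). These were lin-28 (rank 239), lin-14 (905), dre-1 (1201), lin-42 (1345), hbl-1 (1931), lin-66 (2233), daf-12 (3245) and lin-41 (4151), while lin-29, lep-2, lin-46 and blmp-1 were not bound. Both lists hold lin-42 and blmp-1.

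The molting list, genes with defective molting when lost, did not pass the threshold at 9 of 24 bound (37.5%, odds ratio 2.49, Fisher's exact test, adjusted p = 0.0820). The bound members were noah-2 (rank 287), sym-1 (488), ptr-4 (1031), pan-1 (1376), noah-1 (1586), mlt-9 (3102), qua-1 (3621), mlt-7 (4121) and let-767 (4215). The list passed when each summit was assigned to its nearest start within 3000 bp (odds ratio 6.84, Fisher's exact test, adjusted p = 2.34e-05) and with a window of 3000 bp upstream (odds ratio 5.07, Fisher's exact test, adjusted p = 0.000413). The nearest summits to the 15 unbound members lay from 587 bp (fbn-1) and 886 bp (acn-1) to 49881 bp (nekl-2) and 57972 bp (mlt-2) from a start. Those of fbn-1 and acn-1 lay downstream of the start, beyond the 500 bp of the window on that side.

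Of the epidermal junction and attachment list, 9 of 16 were bound (odds ratio 5.34, Fisher's exact test, adjusted p = 0.00371), among them vab-10, a spectraplakin (rank 1547), hmp-2, a beta-catenin (rank 1888), hmr-1, the cadherin (rank 2083), and let-413 (rank 2231). Of the fatty acid synthesis list, 9 of 19 were bound (odds ratio 3.74, Fisher's exact test, adjusted p = 0.0148), among them the desaturase genes fat-2 (summit 1222 bp upstream), fat-3 (rank 474) and fat-6 (rank 3120) and the fatty acid synthase gene fasn-1 (rank 355). Both calls were lost with a window of 500 bp upstream (adjusted p = 0.792 for each by Fisher's exact test) and with the 2472 strongest peaks (adjusted p = 0.253 and 0.737 by Fisher's exact test), and the fatty acid call also with replicate 1's strongest peaks alone (adjusted p = 0.117 by Fisher's exact test).

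Chemoreceptors and F-box A genes, both large families, were bound less often than other genes. Of 751 chemoreceptors 18 were bound (2.40%, odds ratio 0.0976, Fisher's exact test, adjusted p = 5.26e-46), with srh-16 and sri-5 the strongest, and of 170 F-box A genes 5 (2.94%, odds ratio 0.124, Fisher's exact test, adjusted p = 1.27e-09), with fbxa-90 the strongest. Against circular shifts, which keep neighbouring genes together, 18 bound chemoreceptors stood against a mean of 56.2 and 5 bound F-box A genes against 15.3. The adjusted permutation p was 0.00278 for chemoreceptors and 0.0466, just under the threshold, for F-box A genes. Marker lists of other tissues did not pass the threshold. Most of them are too small to be called as bound less often. A list with 0 of 8 bound gave p = 0.368, and a gene family with 0 of 17 bound p = 0.0579 (Fisher's exact test, unadjusted). Bound were 1 of 16 intestinal genes (vit-2), 2 of 14 body wall muscle genes (unc-97 and unc-45), 0 of 8 pharyngeal genes, 2 of 23 neuronal genes (snb-1 and ric-19) and 1 of 17 germ line genes (cgh-1). The other lists that did not pass were cuticlin and precuticle genes (13 of 50, with lpr-4 at rank 41 and lpr-3 at rank 68), patched-related genes (9 of 26, with ptr-15), hedgehog-related genes (9 of 59, with grl-17 and wrt-10), astacin proteases (3 of 37, with nas-24), nuclear receptors (61 of 274, with nhr-14 and nhr-34), epidermal transcription factors (4 of 13, with elt-1 and elt-3), the abu family (1 of 14, abu-13) and histones (11 of 72, with his-37 at rank 17). With each summit assigned to its nearest start, nuclear receptors (73 of 274), epidermal transcription factors (8 of 13), patched-related genes (11 of 26) and cuticlin and precuticle genes (16 of 50) passed the threshold (adjusted p = 0.000147, 0.000812, 0.00389 and 0.0134 by Fisher's exact test). Nuclear receptors also passed it with replicate 2's strongest peaks alone (71 of 274, odds ratio 1.47, Fisher's exact test, adjusted p = 0.0173).

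**Figure D3:**
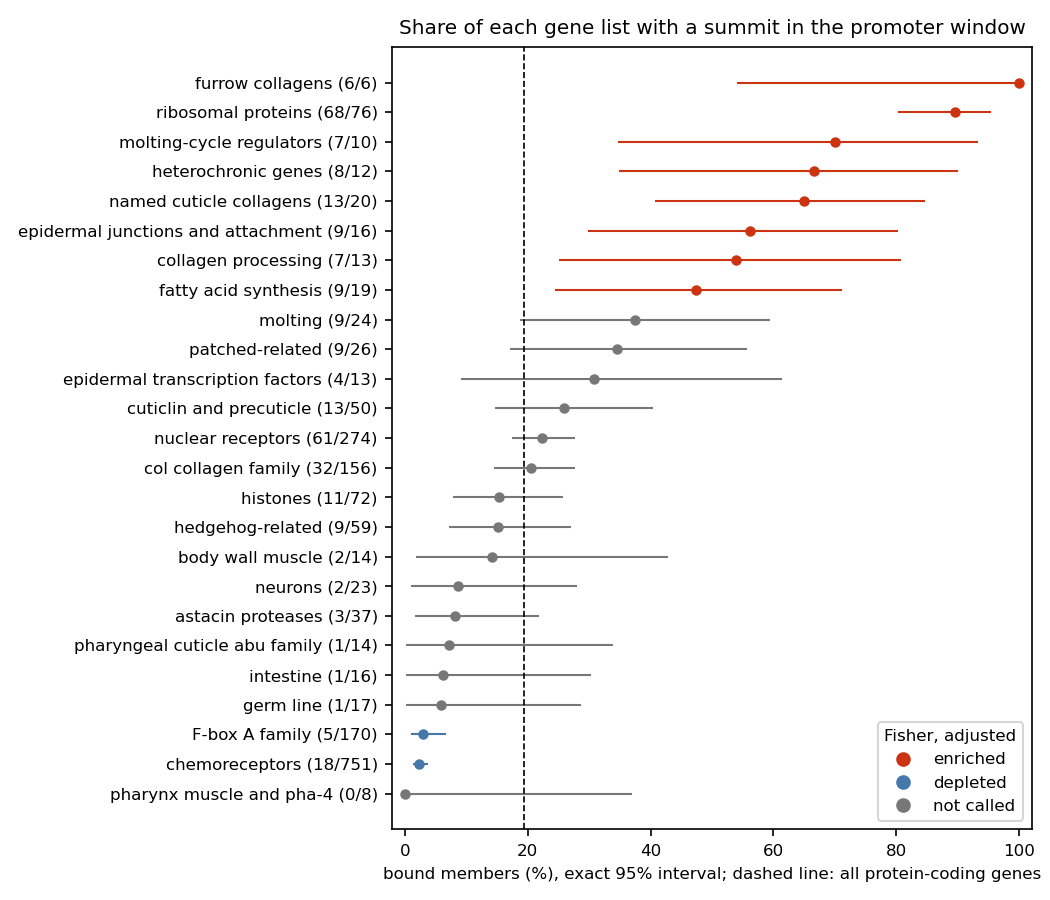
Percentage of each gene list with a thresholded summit in the promoter window (x axis) for 25 lists (y axis, bound and total members in brackets), with exact 95% intervals; the dashed line marks 19.4% of all protein-coding genes. Ribosomal protein genes stand at 89.5% and chemoreceptors at 2.40%.

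Sequence at the summits was examined for the nuclear receptor element RGGTCA and for other motifs. RGGTCA lay within 50 bp of 542 summits (10.96%, exact 95% interval 10.1 to 11.9) against 4.25% of flanking windows (odds ratio 2.78, Fisher's exact test, adjusted p = 5.14e-51), while the same bases in reverse order were at 5.46% against 5.61% (adjusted p = 0.732 by Fisher's exact test). The full ROR response element, WAWNTRGGTCA, was at 54 summits (1.09%) against 0.283% of flanks (odds ratio 3.89, Fisher's exact test, adjusted p = 4.42e-09). Its reversed control was also above flanks, at 16 summits (0.324%) against 0.0708% (odds ratio 4.58, Fisher's exact test, adjusted p = 0.000721), so the odds ratio of the full element did not exceed that of its control. The GA-rich string GAGAGA was at 26.5% of summits against 5.51% of flanks (odds ratio 6.17, Fisher's exact test, adjusted p = 5.65e-271). Runs of T (TTTTTTTT) were at 4.33% against 11.6%, and E-boxes (CANNTG) at 39.6% against 31.1% (adjusted p = 3.72e-52 and 1.97e-24 by Fisher's exact test). GATA sites were at 31.8% against 25.8% and their reversed control at 28.0% against 24.0% (adjusted p = 1.56e-13 and 3.15e-07 by Fisher's exact test). The grainyhead site was at 0.870% against 0.202% (adjusted p = 3.48e-08 by Fisher's exact test) and the extended element TCAAGGTCA at 0.202% against 0.0506% (adjusted p = 0.0140 by Fisher's exact test). The extended element was at 10 summits and 5 flanking windows only, and no reversed control was run for either string. BLMP-1 and AP-1 sites did not pass the threshold (adjusted p = 0.0636 and 0.652 by Fisher's exact test). Peaks with RGGTCA had a median rank of 2460.5, and peaks without it 2476.5 (permutation p = 0.892). For the full ROR element the median ranks were 2264.5 and 2475.5 (permutation p = 0.528). With replicate 1's strongest peaks alone, the difference for the full element was −882 ranks (permutation p = 0.0113).

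**Figure D4:**
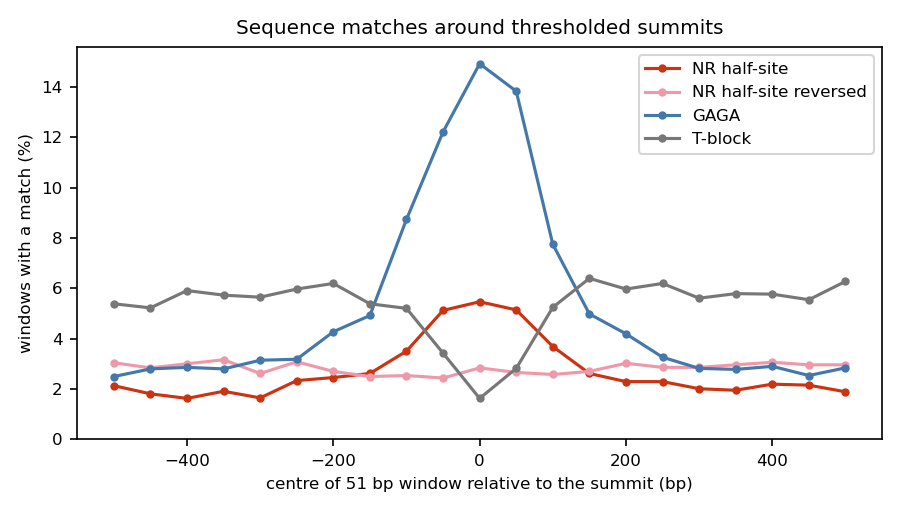
Percentage of windows of 51 bp holding a match (y axis) by the position of the window centre relative to the thresholded summit (x axis, bp), for RGGTCA, its reversed control, GAGAGA and runs of T. At the summit GAGAGA reaches 14.9% and RGGTCA 5.46%, while runs of T fall to 1.62%.

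Chromosome X held 998 peaks, 20.2% of the total against 17.7% of the genome's length, or 56.3 peaks per Mb against 47.8 on autosomes (ratio 1.18, exact binomial p = 5.33e-06). Chromosome III had a higher density than X, at 60.3 peaks per Mb, and chromosome V the lowest, at 36.8. Of the genes on X 19.04% were bound, against 19.4% of all protein-coding genes, 25.4% on chromosome I and 27.5% on chromosome III.

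The nhr-23 and unc-119 loci were examined because the strain's transgene targets nhr-23 and the strain carries an unc-119 mutation. No thresholded peak lay within 20 kb of nhr-23 (chromosome I, 7214745 to 7221299), where 2.30 would lie at the genome's average density. Replicate 1's list had 3 peaks there and replicate 2's list had 0, against averages of 13.9 and 12.6. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935), 2 thresholded peaks were found, the stronger at rank 2861. The molting gene mlt-2, listed as unbound, lies inside the same peak-free stretch as nhr-23.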

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

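The test in this part was chosen after the main results were seen. The pooled list held 25056 peaks below the authors' threshold, which are otherwise used only to count peaks around genes. RGGTCA lay within 50 bp of 5.84% of their summits, against 4.09% of their flanking windows (odds ratio 1.45, Fisher's exact test, p = 5.27e-26), and its reversed control was at 5.91% against 6.38%. GAGAGA was at 9.14% against 5.86%. No biological explanation was tested for this signal.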

How the results depend on the processing

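The alternatives that kept only peaks among the 4944 strongest of both replicates, or left out ribosomal protein genes, their peaks or the egl-5 interval, were chosen after seeing the data, as were those for RGGTCA and GAGAGA. Of 440 alternative values, 322 kept their direction and side of the threshold or, for counts with no test, stayed within 1.5 times the reported value, and 64 more equalled the reported value by construction or coincidence, including those from the 4944 strongest pooled peaks, which are the thresholded list and test nothing. Another 16 passed the threshold newly, 14 lost it, 11 moved and 13 reversed. The promoter share ranged from 47.3 to 77.8% and the X to autosome ratio from 1.17 to 1.60, all past the threshold. The number of lists called ranged from 7 to 15 around the reported 10, and that of bound genes from 2283 to 4949. Of 808 alternative calls of named genes 80 changed. The lists carry no depth, so weak peaks cannot be judged by it. The cause was not tested for any change below, except that fewer peaks or genes enter some settings.

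With the 2472 strongest peaks, 2283 genes were bound, and 2 lists passed the signal test. Odds ratios there were 3.45 for collagen processing, 2.59 for epidermal junctions and 1.45 for fatty acid synthesis, none past the threshold, and 0.703 for the col family and 0.880 for nuclear receptors, which reversed without passing it. Replicate support of the thresholded peaks was 98.8% for an overlap of 1 bp, 93.4% for 50% of the peak, 93.2% for summits within 100 bp, 67.4% for the 4944 strongest peaks of each replicate and 91.7% for the 9888 strongest. The overlap of the replicates' strongest peaks was 70.1% for 1000 and 59.5% for 9888 peaks.

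Without 1 replicate, odds ratios ranged from 3.58 to 3.84 for collagen processing (both below the threshold), from 2.61 (without replicate 2, below it) to 3.76 for fatty acid synthesis and from 0.994 to 1.02 for the col family. The number of lists passing the signal test ranged from 1 to 2, and the rank difference of the full ROR element from −882 to −420.5. Among peaks supported by both replicates, odds ratios were 2.97 for molting (past the threshold), 3.71 for collagen processing and 2.74 for fatty acid synthesis (both below it), 0.973 for the col family and 0.984 for nuclear receptors.

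The molting list passed the threshold with a window of 3000 bp (5.07), with the nearest start (6.84), among genes with 1000 bp upstream (4.52) and against lists matched on upstream gap (2.72). Lists that passed the threshold newly also included nuclear receptors without replicate 1 (1.47), with the nearest start (1.78) and among genes with 1000 bp upstream (1.71), epidermal transcription factors with a window of 3000 bp (4.86) and the nearest start (7.80), patched-related genes in both of these (2.61 and 3.58) and against matched lists (2.79), cuticlin and precuticle genes with the nearest start (2.30), and histones, bound less often, against matched lists (0.463). Ribosomal proteins kept the call with the nearest start at 5.18 and had odds ratios from 27.9 to 55.4 in the other settings. With a window of 500 bp, collagen processing (2.78), epidermal junctions (1.44) and fatty acid synthesis (1.17) lost it. Among genes with 1000 bp upstream, furrow collagens (25.8), collagen processing (4.30) and fatty acid synthesis (2.87) lost it, and the col family (0.943) and histones (7.74) reversed, as did histones with tandem genes counted once (1.53), none of these past it. The rank difference between peaks with and without RGGTCA was 63 among the 2472 strongest peaks, 71.5 among peaks supported by both replicates and 216.5 in a window of 25 bp, and that of the full ROR element was 214.5 and 31 in the first 2 of these; none passed the threshold.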

Other observations

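Apart from the test of RGGTCA at cuticle and molting genes, the tests in this part were chosen after the results they rest on were seen. Among 170 gene families with at least 10 members sharing a name stem, 20 were bound more often than other genes and 27 less often. Beyond ribosomal proteins of the cytosol, bound families included dpy (17 of 25, adjusted p = 3.61e-06), which shares members with the collagen lists, wdr (11 of 15, adjusted p = 0.000143), the proteasome subunits rpn (10 of 13, adjusted p = 0.000173), the chaperone cofactors dnj (16 of 29, adjusted p = 0.000217), the cyclophilins cyn (11 of 16, adjusted p = 0.000244), the mitochondrial ribosomal proteins mrpl (19 of 41, adjusted p = 0.000689), the nuclear pore proteins npp (14 of 26, adjusted p = 0.000747) and the vacuolar ATPase subunits vha (11 of 20, adjusted p = 0.00263), all by Fisher's exact test. The other mitochondrial ribosomal protein family, mrps, did not pass the threshold (8 of 25, adjusted p = 0.260 by Fisher's exact test). The C-type lectins clec were bound at 5 of 240 (2.08%, adjusted p = 1.02e-14 by Fisher's exact test). Of 2080 strings of 6 bases, 846 were more frequent at summits than in flanks past the threshold, so a higher share at summits is not particular to the motifs fixed in advance. Among them, CGCGCG (4.83% of summits against 0.556% of flanks) and ACGCAG (13.9% against 1.95%) had the highest odds ratios, 9.08 and 8.12. The microRNA genes lin-4, mir-48, mir-84 and mir-241 each had a thresholded summit in the window, 379, 194, 555 and 444 bp upstream of the annotated microRNA gene. The share of all microRNA genes with such a summit was not determined, so these 4 cannot be set against a background. The fifth microRNA member of the heterochronic list was not matched by name in the annotation and was not assessed.

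A hypothesis stated before its test was that peaks at cuticle and molting genes carry the receptor's element more often. RGGTCA was at 21 of 78 peaks (26.9%, exact 95% interval 17.5 to 38.2) in the windows of the molting, collagen, cuticlin and collagen processing lists, against 9.23% of other promoter peaks outside ribosomal protein genes (odds ratio 3.62, Fisher's exact test, p = 8.18e-06, adjusted p = 5.23e-05 over 9 comparisons). GAGAGA was at 24.4% against 25.7% (Fisher's exact test, p = 0.896). Promoter peaks as a whole carried RGGTCA less often than peaks outside promoter windows (9.50% against 13.6%, odds ratio 0.665, Fisher's exact test, adjusted p = 5.23e-05). Neither the flanks of the 78 cuticle and molting peaks nor the reversed control was examined for this group. A higher local background of RGGTCA at these genes therefore stays open. That the receptor contacts its element at a larger part of these peaks than of other promoter peaks remains a hypothesis. A motif share does not measure contact.

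Ribosomal protein promoters were bound with strong peaks. Neighbouring genes do not account for all of this, since random lists matched on upstream gap were bound at a mean of 23.3% and the list stayed past the threshold with each summit assigned to its nearest start, but there 51.3% of its genes were bound, so peaks of neighbouring genes behind part of the calls stay open. A single replicate does not account for it, since the odds ratio was at least 31.6 with either replicate's strongest peaks alone. RGGTCA was at 1 of 69 of these peaks (1.45%), against 11.1% of other thresholded peaks (Fisher's exact test, p = 0.00562, adjusted p = 0.0126 over 9 comparisons). Other promoter peaks, the closer comparison, held it at 9.68% (Fisher's exact test, p = 0.0194, adjusted p = 0.0349). A signal at active promoters without the receptor's element would give such a lower share. The share was also below that of these peaks' own flanks, 12.3% (Fisher's exact test, p = 0.00774). These flanks held RGGTCA more often than the flanks of all thresholded peaks, at 4.25%. The exact 95% interval of the share at the 69 peaks, 0.0367 to 7.81%, holds that 4.25%. The comparison with their own flanks therefore cannot decide for or against such a signal. Transcription, chromatin accessibility and the control were not analysed here, so recruitment through other proteins and non-specific enrichment stay open, and no biological explanation was tested, since all samples are of 1 group.

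The interval at egl-5 was the strongest in both replicates and the widest of the thresholded list, at 2666 bp against 1163 bp for the next. Repeated sequence is argued against, since 0% of its 2617 strings of 50 bases occur elsewhere in the nuclear genome, and so is egl-5 cDNA, since each replicate's list had at least 2 summits in introns or unannotated parts of the gene. A candidate explanation is a genomic egl-5 fragment of fixed ends in the samples, since the interval's ends differed by at most 8 bp between replicates, against a median of 34.5 bp for 6 other wide intervals, too few to decide. None of the 4 thresholded summits had RGGTCA or GAGAGA within 50 bp, and a fragment and binding along the gene cannot be told apart here because the reads and the control were not analysed.

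The stretch around nhr-23 held 2 pooled peaks within 20 kb, and the pooled list left 80.1 kb with 22 gene starts around the gene without a summit, against 48.3 kb with 12 gene starts in replicate 1's list and 83.1 kb with 22 in replicate 2's. As few peaks were found at 18.2% of protein-coding genes and at 8.30% of those on chromosome I, so such a count is not rare among genes. Of all genes with as few, 41.0% lie on chromosome V, where peak density was lowest, and neighbouring genes share windows. These shares therefore do not measure chance, and a chance absence of peaks stays open. Only 58 of 29994 stretches between pooled summits (0.193%), and 0.397% of those between replicate 1's, held as many gene starts. Those are shares of stretches, most of them short, and do not give how often a gene lies in such a stretch. Pooled peaks within 20 kb of unc-119 were not scarce, since 61.0% of genes had as few. This cannot decide whether extra transgene copies lower the call at both loci. Whether and how far the transgene copies the sequence around unc-119 was not examined. Copies acting at nhr-23 alone cannot be told apart from chance without the control: 0 pooled peaks lay within 10 kb, where 7.94 would lie at the genome's average.

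The strongest peaks of the 9 bound molting genes ranked higher in replicate 2 than in replicate 1 for 7 genes, with a median shift of 24.4 percentiles among peaks found in both lists (permutation p = 0.00768, adjusted p = 0.0653 over 17 lists). Replicates taken at different points of the molting cycle could give such a shift, but it did not pass the adjusted threshold. Nuclear receptors had a smaller shift in the same direction with as low a p, 7.06 percentiles (permutation p = 0.00672, adjusted p = 0.0653), while molting-cycle regulators shifted by −1.03 percentiles (permutation p = 0.817). Whether the samples differed in developmental time cannot be told apart from other differences between the 2 replicates.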
